A study of Mus musculus with 10 samples.

How the data were processed

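RNA was measured in 10 libraries of mouse hippocampal CA3, 5 injected with virus carrying a scrambled hairpin and 5 with virus carrying an shRNA against Mef2c. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was made into cDNA libraries and these were sequenced as read pairs on an Illumina HiSeq instrument. Per the submitters' processing notes the reads were processed with HISAT2 and featureCounts, with mm10 as the genome build; versions, settings, strandedness, the annotation and any filter on rows are not given in the sources used here. The deposited values are raw counts per gene, whole numbers with no normalization, as the values in the files show. Each table holds the same 18453 Ensembl identifiers, of which 18421 are in GENCODE M21 (GRCm38, the same assembly as mm10) and 32 are not. Of the matched rows 18392 are protein-coding and 29 of other types, the lowest total of a row over the 10 libraries was 1, and 0 rows were unnamed or summary rows. Without knowledge of strand, reads of overlapping or antisense genes cannot be told apart, and reads shared by close gene copies, such as ribosomal protein genes and their pseudogenes, remain uncertain. Xist was not analysed here.

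Groups and replicate numbers came from the sample titles. In the library titled knockdown 1 the treatment tag is misspelt, and the title gave its group. Library totals ranged from 14701928 to 17798090 counts, at which counting error is small for all but the lowest genes, and the spread between libraries sets the precision. No library duplicated another: within groups, chi-square per degree of freedom between counts lay between 3.85 and 39.2. Gene symbols, coordinates, and the length and GC content of the longest transcript came from GENCODE M21.

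Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, normalized with TMM and tested with the robust quasi-likelihood test of knockdown against scramble without further terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the standard error of a log2 fold change was its size divided by the square root of F. Of the genes, 14393 were tested. CPM values are normalized to the TMM-scaled library size, those of the sex-linked genes to the plain total, and log2 CPM used a prior count of 2. The 43 gene lists, each with at least 3 tested members, were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation of 0.01, with adjustment over the lists, and also with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether its genes move on balance in a common direction. List scores are the mean log2 CPM of the members, each centred over the 10 libraries, and were compared with exact two-sided permutation tests over all 252 assignments. Mef2c was also tested that way on log2 of CPM plus 1.

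Before the data were examined, the groups, tests, lists, alternatives and a rule for the genes named in the text were fixed. The rule takes Mef2c and its family, the 12 higher and the 12 lower genes with the smallest p among called genes with a mean of at least 2 CPM and without clone-like names, up to 4 genes with the smallest p in each list described, and the sex-linked transcripts as a check of the labels. Hcn2, Kcnip2, Bcl11b, Cux2 and Lamp5 were named after their values were seen. Some genes the rule takes are not reported here. Mef2b was not tested, since its counts were too low for the filter. The alternatives fixed with them were 2 other normalizations (DESeq2 size factors and upper quartiles), 2 other filters, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, a replicate block, 1 surrogate variable from sva 3.50.0, marker scores of dentate granule cells and of oligodendrocytes as covariates, other thresholds, and leaving out each library in turn. Chosen after seeing the data were covariates for the cortical, interferon, microglia and choroid plexus scores, the removal of sets of libraries, thinning of all libraries to the lowest total, and 2 corrections for transcript properties. The first of these fits natural splines with 5 degrees of freedom of log2 length and of GC content to each library's deviation from the gene mean and uses them as offsets. The second also extends each transcript to the RefSeq 3' end of the same assembly where that lies up to 20 kb past the GENCODE end, with genes matched by symbol, chromosome and overlapping spans.

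The pipeline was tested on simulated counts of 14281 genes drawn from the means of these libraries, with 200 genes and the heat shock list changed. In the knockdown against scramble comparison edgeR recovered 75% of genes changed 1.5-fold and 86% of those changed 2-fold, and called 10 unchanged genes. With nothing changed (14289 genes) it called 0. With a trend along transcript length added, it called 364 unchanged genes of 14303, and 7 of 14291 after the correction. The simulated trend was linear in log2 of the annotated length and the same in all knockdown libraries, without a GC effect. These counts do not show how the correction does where lengths are misstated or slopes differ between libraries. Apart from the added trend, each gene was drawn independently of the others. The counts of unchanged genes therefore do not cover shifts that many genes of a library share. In 100 splits of the libraries into groups of 5, the real one included, the numbers of called genes and lists were recounted.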

Results

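Gene-level read counts of 10 RNA-seq libraries were compared, all from CA3, the field of the mouse hippocampus whose pyramidal neurons receive mossy fibre input from the dentate gyrus. The mice were of strain C57BL/6J and received adeno-associated virus on both sides of the brain by stereotaxic injection. In 5 libraries the virus carried a short hairpin RNA (shRNA) against Mef2c, a transcription factor that regulates neuronal survival and synapse number, and in the other 5 it carried a scrambled hairpin. The series concerns a mouse model of anxiety and names several brain regions, of which CA3 is the region analysed here. Total counts ranged from 14701928 to 17798090 per library. They averaged 15055829 ± 352983 (SD, n = 5) in the scramble libraries and 16617794 ± 833318 (SD, n = 5) in the knockdown libraries. Every knockdown library was deeper than every scramble library, with an exact two-sided permutation p of 0.0079, the smallest that 5 against 5 libraries allow. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in all 10 libraries, with Ddx3y between 54.0 and 72.1 CPM, the usual unit of counts scaled to library size. The labels give a male sex for each library, although the injection protocol speaks of mice of either sex. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries.

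Mef2c, the targeted gene, lies on chromosome 13 (positions 83504034 to 83667080, plus strand, GRCm38, identifier ENSMUSG00000005583). Its transcript level was 205 ± 60.7 CPM (SD, n = 5) in the scramble libraries and 162 ± 71.9 CPM (SD, n = 5) in the knockdown libraries. The difference was smaller than the spread between libraries: the log2 fold change was -0.34 (SE 0.30, edgeR quasi-likelihood adjusted p = 0.489), and an exact two-sided permutation test of 252 assignments gave p = 0.246. In scramble libraries 1 to 5, Mef2c stood at 166, 198, 176, 312 and 175 CPM. In knockdown libraries 1 to 4 it stood at 111, 131, 121 and 163 CPM, each below the lowest scramble library. The library labelled knockdown 5 stood at 286 CPM, above all scramble libraries except number 4. Scramble library 4 and the library labelled knockdown 5 also had the highest score of cortical layer neuron markers within their groups, 0.44 and 0.80 in log2 units. With that score as a covariate, chosen after seeing the data, the Mef2c log2 fold change was -0.34 (SE 0.083, edgeR adjusted p = 0.0123). Without those 2 libraries it was -0.45 (SE 0.105, edgeR adjusted p = 0.0274). With the microglia marker score as a covariate, which itself averaged -0.27 in scramble and 0.27 in knockdown libraries, it was 0.18 (SE 0.34). It also shrank, without passing, to -0.163 with 1 surrogate variable, -0.107 with a correction for transcript length and GC content described below, -0.115 with RefSeq 3' ends in that correction, -0.048 with the interferon score and -0.056 without knockdown libraries 2, 3 and 4. It was -0.64 (edgeR adjusted p = 0.0877) without the library labelled knockdown 5 alone and -0.14 (edgeR adjusted p = 0.799) without scramble library 4 alone. The related factors Mef2a and Mef2d did not pass the test, with log2 fold changes of -0.10 (SE 0.07) and -0.14 (SE 0.09).

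**Figure D1:**
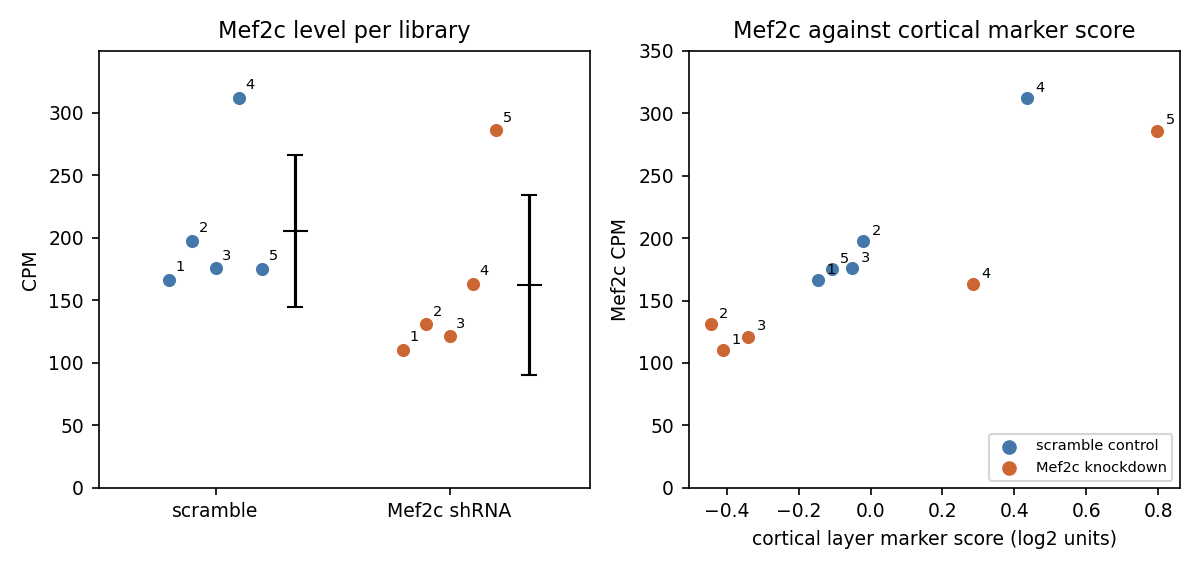
Left, Mef2c in CPM for each library, numbered by replicate, with the mean and SD of each group of 5 in black. Right, the same CPM against the score of cortical layer neuron markers in log2 units; scramble library 4 (312 CPM) and the library labelled knockdown 5 (286 CPM) have the highest scores of their groups.

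Gucy1a2, a subunit of the nitric oxide receptor guanylate cyclase, fell from 7.77 ± 0.745 to 2.14 ± 0.471 CPM (log2 fold change -1.86, SE 0.17), and Dgki, a diacylglycerol kinase, fell from 43.1 ± 2.24 to 17.8 ± 4.14 CPM (-1.28, SE 0.13). The ryanodine receptors Ryr2 and Ryr3, calcium release channels of the endoplasmic reticulum, fell with log2 fold changes of -0.72 (SE 0.071) and -0.75 (SE 0.086). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 6.96 ± 1.34 to 19.5 ± 7.18 CPM, and the microglial complement gene C1qa rose from 37.3 ± 9.82 to 93.6 ± 42.2 CPM. All these values are means ± SD of 5 libraries, and each change passed the edgeR test. In Gucy1a2, Dgki, Ryr2 and Cdkn1a, all 5 knockdown libraries, the library labelled knockdown 5 included, lay beyond all 5 scramble libraries. After a correction for transcript length and GC content, described below, the log2 fold change was -0.24 (SE 0.047) for Ryr2, -0.29 (SE 0.054) for Ryr3 and 1.325 (SE 0.247) for Cdkn1a, and C1qa no longer passed (1.07, SE 0.341, edgeR adjusted p = 0.156).

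Of 14393 genes tested with edgeR, 1766 passed an adjusted p of 0.05, 671 of them higher and 1095 lower in the knockdown libraries, and 38% of the calls were higher. At an absolute log2 fold change of at least 1, 54 were higher and 51 lower. The groups did not overlap in 1344 genes, 9.3% of those tested, where chance gives 0.79%. With 1 surrogate variable 608 genes passed, 131 of them higher. With the microglia marker score as a covariate, chosen after seeing the data, 16 passed, 0 higher and 16 lower. That score itself averaged -0.27 in the scramble and 0.27 in the knockdown libraries, so this fit cannot part the group from the score. The biological coefficient of variation between libraries was 15.2%. Leaving out a single library moved the count to between 631 (scramble library 2) and 3305 (knockdown library 1). It was 990, 758 and 674 without scramble libraries 1, 4 and 5, and 737, 1137 and 1061 without knockdown libraries 2, 3 and 4. Without knockdown libraries 2, 3 and 4 together, an alternative chosen after seeing the data, edgeR called 0 genes, and 2590 had an unadjusted p under 0.05. That leaves knockdown library 1 and the library labelled knockdown 5, whose counts differed most within a group (chi-square per degree of freedom 39.2). A loss of power cannot be told apart there from a loss of effect.

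The 12 lower genes with the smallest p were Gucy1a2, Arfgef3, Ryr2, Usf3, Dgki, Nexmif, Tenm1, Csmd3, Ryr3, Ash1l, Unc80 and Ago3. Besides the receptors and the kinase, they include Unc80, a component of the sodium leak channel complex, Ash1l, a histone methyltransferase, Ago3, an Argonaute protein of small RNA silencing, and the transmembrane proteins Tenm1 and Csmd3. Arfgef3 (chromosome 10, 18581839 to 18743949) fell from 199 ± 16.9 to 126 ± 5.45 CPM (log2 fold change -0.66, SE 0.066, edgeR adjusted p = 0.000329). Gucy1a2 lies on chromosome 9 (3532778 to 3894736) and Dgki on chromosome 6 (36846022 to 37300184), and their edgeR adjusted p values were 0.000329 and 0.000338. The RefSeq gene ends 11055 bp past the GENCODE 3' end of Gucy1a2, 8641 bp past that of Dgki and 4710 bp past that of Ago3. Tenm1 (-1.08, SE 0.117) and Nexmif (-0.74, SE 0.080), an X-linked gene of neuronal development, fell as well.

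The 12 higher genes with the smallest p were Adrm1, Eng, Dcxr, Ftl1, Dcakd, Trafd1, Mov10, Nop53, Pik3ip1, Ccm2, Cyba and Sh3bgrl3. Adrm1, a ubiquitin receptor of the proteasome (chromosome 2, 180171485 to 180176286), rose from 63.9 ± 4.34 to 85.9 ± 5.25 CPM (log2 fold change 0.43, SE 0.065, edgeR adjusted p = 0.00173). Eng, the endothelial co-receptor endoglin (chromosome 2, 32646595 to 32682669), rose from 26.9 ± 0.547 to 37.8 ± 3.79 CPM (0.49, SE 0.076, edgeR adjusted p = 0.00189). Ftl1, the ferritin light chain, rose by a log2 fold change of 0.59 (SE 0.10). Cyba, a subunit of the NADPH oxidase of phagocytes, rose by 1.25 (SE 0.22).

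**Figure D2:**
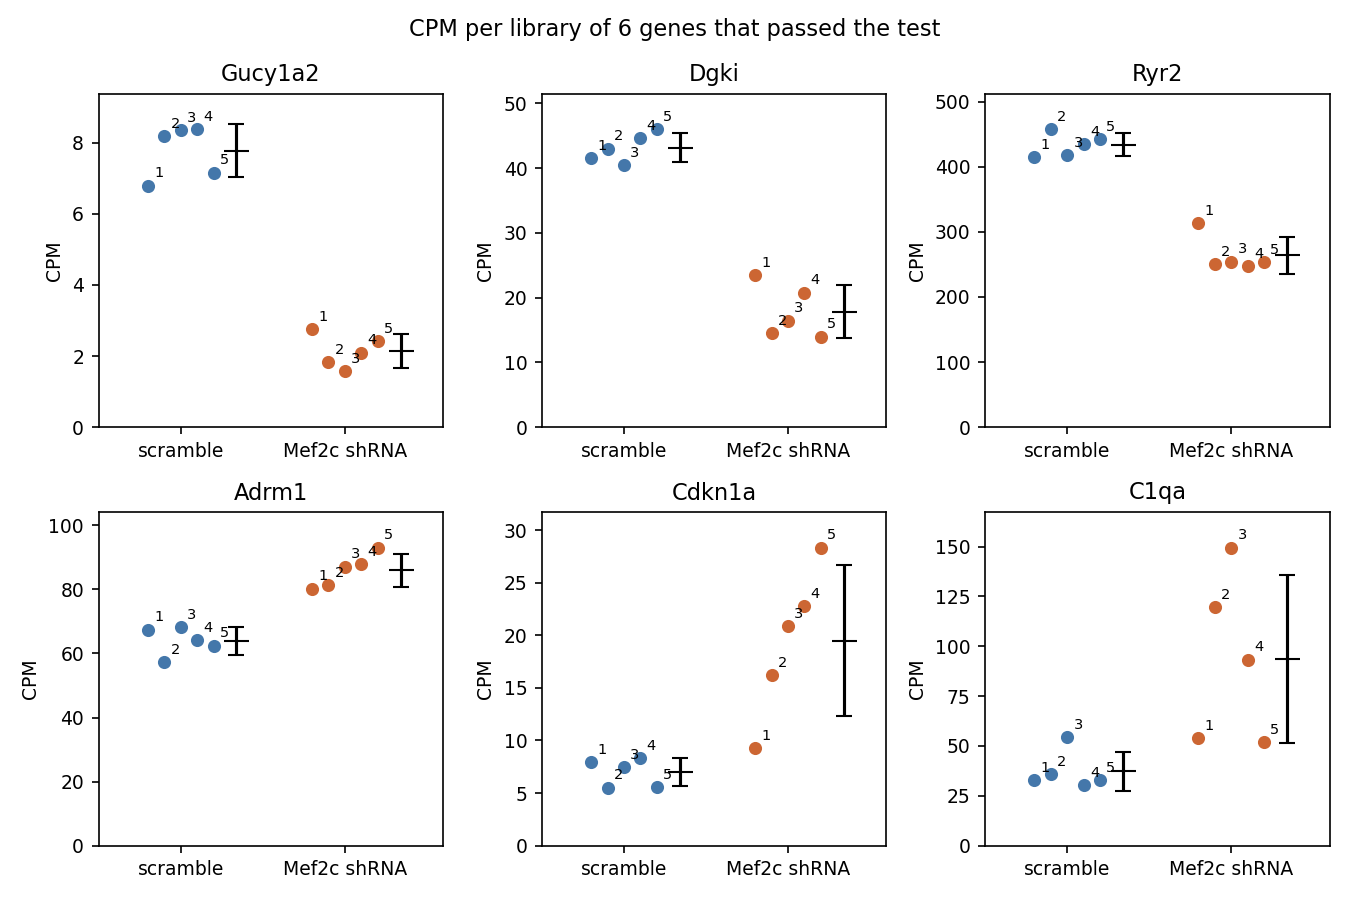
CPM of Gucy1a2, Dgki, Ryr2, Adrm1, Cdkn1a and C1qa in each library, numbered by replicate, with the mean and SD of each group of 5 in black; every axis starts at 0. The knockdown libraries lie beyond all scramble libraries in the first 5 genes, and C1qa overlaps, with scramble library 3 at 54.5 CPM.

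Fold changes followed transcript length. Genes with transcripts under 1 kb had a median log2 fold change of 0.26, those of 2 to 4 kb of 0.06 and those over 12 kb of -0.48, and the Spearman correlation across 14381 genes was -0.563, with genes not being independent replicates. The median transcript length was 1.98 kb for the genes that rose, such as Dcxr and Cyba, and 7.48 kb for those that fell, such as Ryr2 and Arfgef3. Across the same genes, the Spearman correlation of the log2 fold change was -0.457 with gene span, introns included, and 0.321 with GC content. In a joint fit with transcript length and GC content, gene span kept a slope of -0.0262 per doubling. The correction below leaves span out. In each library, log2 CPM, centred for each gene over the 10 libraries, was fitted on log2 length together with GC content. The length slope was 0.078 ± 0.026 (SD, n = 5) in the scramble libraries and -0.078 ± 0.077 (SD, n = 5) in the knockdown libraries (exact two-sided permutation p = 0.0159). Centring makes the 2 means mirror each other, so their difference is informative and their signs are not. Knockdown library 1 had a slope of 0.045, within the range of the scramble libraries. A per-library correction for length and GC content, chosen after seeing the data, left 237 genes called, 101 higher and 136 lower, of which 171 were also called without it, 170 in the same direction. The median length was now 6.46 kb for the higher and 4.26 kb for the lower genes. Some higher genes with long annotated transcripts had changed little without it, such as Hnrnpr (0.473 from -0.087) and Ube2d3 (0.581 from 0.011). Whether their longest transcript overstates their length was not tested. After the correction, Gucy1a2 (-1.84, SE 0.18), Dgki (-1.25, SE 0.11) and Ryr2 (-0.24, SE 0.047) stayed past the threshold. Ryr3 (-0.29 from -0.747), Nexmif (-0.332 from -0.738), Tenm1 (-0.644 from -1.075) and Ash1l (-0.199 from -0.605) also did, with smaller log2 fold changes. Arfgef3 (-0.185 from -0.663), Usf3 (-0.216 from -0.649), Csmd3 (-0.186 from -0.619), Unc80 (-0.178 from -0.631) and Ago3 (-0.107 from -0.585) did not stay past the threshold. With lengths taken up to the RefSeq 3' ends, Usf3 passed (-0.24, edgeR adjusted p = 0.032). Of the 12 higher genes, Adrm1, Eng, Dcxr, Trafd1 and Nop53 stayed past it, and Ftl1, Dcakd, Mov10, Pik3ip1, Ccm2, Cyba and Sh3bgrl3 did not. Some of these kept most of their log2 fold change, such as Cyba (0.944, SE 0.22, edgeR adjusted p = 0.0509, from 1.25) and Mov10 (0.325, SE 0.078, edgeR adjusted p = 0.0545, from 0.401), and others less of it, such as Ftl1 (0.311 from 0.586), Dcakd (0.188 from 0.389), Pik3ip1 (0.226 from 0.343), Ccm2 (0.169 from 0.355) and Sh3bgrl3 (0.187 from 0.484).

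**Figure D3:**
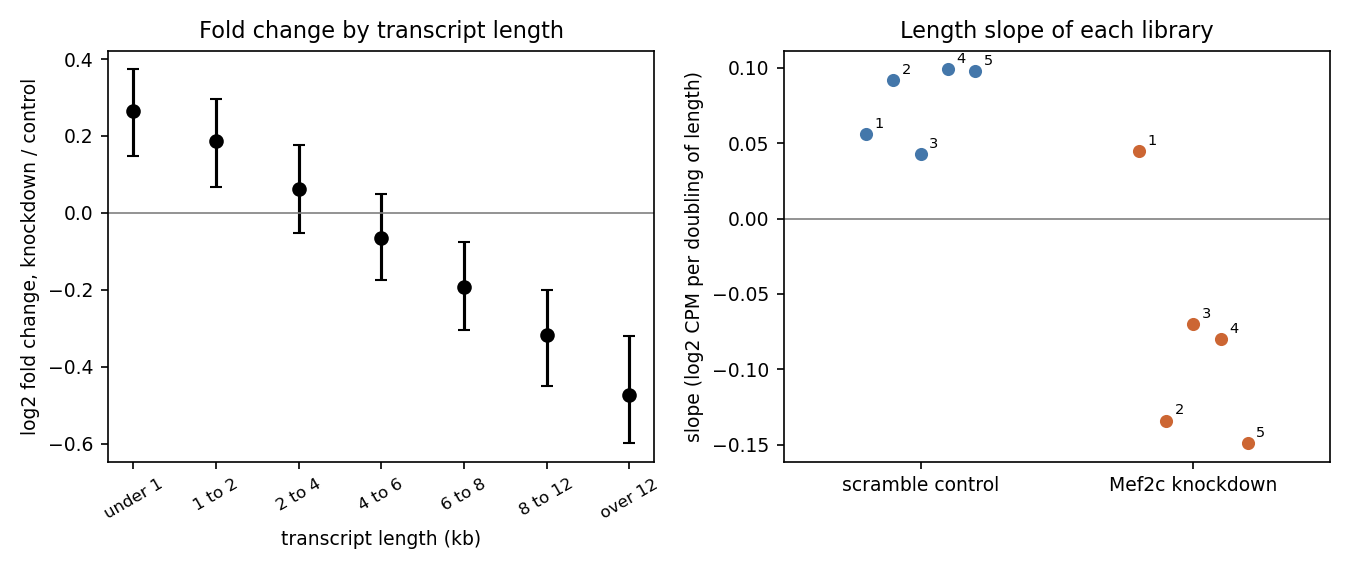
Left, median log2 fold change of the tested genes by transcript length in kb, with bars from the first to the last quartile; the medians run from 0.26 under 1 kb to -0.48 over 12 kb. Right, the slope per doubling of transcript length in each library, numbered by replicate. It was fitted with GC content to log2 CPM centred for each gene over the 10 libraries. Knockdown library 1 (0.045) lies among the scramble libraries.

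Of 43 gene lists, 21 passed camera at an adjusted p of 0.05, 12 higher and 9 lower; with an estimated correlation between genes 0 passed, and the lowest adjusted p was 0.317. Lists of the immune response were among the higher ones, with their highest scores in knockdown libraries 2, 3 and 4. The library labelled knockdown 5 lay within the range of the scramble libraries in the scores of microglia (-0.225), complement (-0.319), reactive astrocyte (-0.276) and activated microglia genes (-0.336), and knockdown library 1 lay below scramble library 3 in those of microglia (0.023 against 0.041), reactive astrocyte and activated microglia genes. Of 14 microglia markers, 6 rose, among them Tmem119 (log2 fold change 0.75, SE 0.15) and the growth factor receptor Csf1r (0.48, SE 0.12), and 9 rose adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Of 18 activated microglia genes, 7 rose, among them Apoe (0.48, SE 0.093), the lysosomal proteases Ctsd (0.57, SE 0.117) and Ctsb (0.26, SE 0.058) and the ferritin heavy chain Fth1, and 13 rose adjusted over the list alone (adjusted p = 0.368 with an estimated correlation). Of 14 complement genes, 4 rose, including C1qa (1.33, SE 0.334) and C3ar1, and 11 adjusted over the list alone (adjusted p = 0.48 with an estimated correlation). Of 19 reactive astrocyte genes, 3 rose, namely S1pr3, the oncostatin M receptor Osmr and Vim, and 11 adjusted over the list alone (adjusted p = 0.328 with an estimated correlation). Of 16 antigen presentation genes, the peptide transport genes Tap2 (1.07, SE 0.244) and Tapbp (0.96, SE 0.249) rose, and 13 adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). After the length and GC correction, the called genes were 1 of the microglia markers (Selplg, 0.60, SE 0.129), 2 activated microglia genes (Ctsb and Fth1), 1 reactive astrocyte gene (Osmr), 0 complement and 0 antigen presentation genes. Adjusted over the list alone, they were 6, 9, 7, 11 and 1 in that order. These lists still passed camera after the correction (adjusted p = 5.59e-05, 1.74e-06, 4.67e-06, 2.05e-05 and 4.67e-06 in the same order). With an estimated correlation none did (adjusted p = 0.485 for each). Apoe (0.24, edgeR adjusted p = 0.066), Ctsd (0.42, 0.109), Tmem119 (0.59, 0.0711), Csf1r (0.495, 0.0642), C3ar1 (1.265, 0.052), S1pr3 (0.91, 0.052), Vim (0.97, 0.116), Tap2 (0.98, 0.0767) and Tapbp (0.84, 0.137) no longer passed.

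The interferon-stimulated genes had a mean log2 fold change of 1.66 over 23 genes, of which Rtp4 (2.05, SE 0.521) rose; adjusted over the list alone, 0 passed (adjusted p = 0.537 with an estimated correlation). Irf7, a master regulator of the interferon response, stood at 5.18 ± 4.58 CPM in the scramble libraries and 27.1 ± 19.6 CPM in the knockdown libraries and did not pass (edgeR adjusted p = 0.102). The list score lay between 1.51 and 1.98 log2 units in knockdown libraries 2, 3 and 4, 0.14 in knockdown library 1 and -1.52 in the library labelled knockdown 5. In scramble libraries 1 to 5 it was -1.55, 0.07, 0.53, -1.30 and -1.47, and the exact two-sided permutation p of the score was 0.111 (0.177 after Benjamini-Hochberg adjustment over the 43 lists). Markers of infiltrating lymphocytes and myeloid cells had a mean log2 fold change of 1.86 over 8 genes, with 0 passing over all genes or adjusted over the list alone (adjusted p = 0.522 with an estimated correlation); Ccl5 stood at 1.18 ± 1.49 and 8.83 ± 9.29 CPM. Of 11 chemokines and cytokines, 0 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Without knockdown libraries 2, 3 and 4, the complement list still passed camera (adjusted p = 0.0339, but 0.726 with an estimated correlation), and the interferon list had a mean log2 fold change of -0.03.

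**Figure D4:**
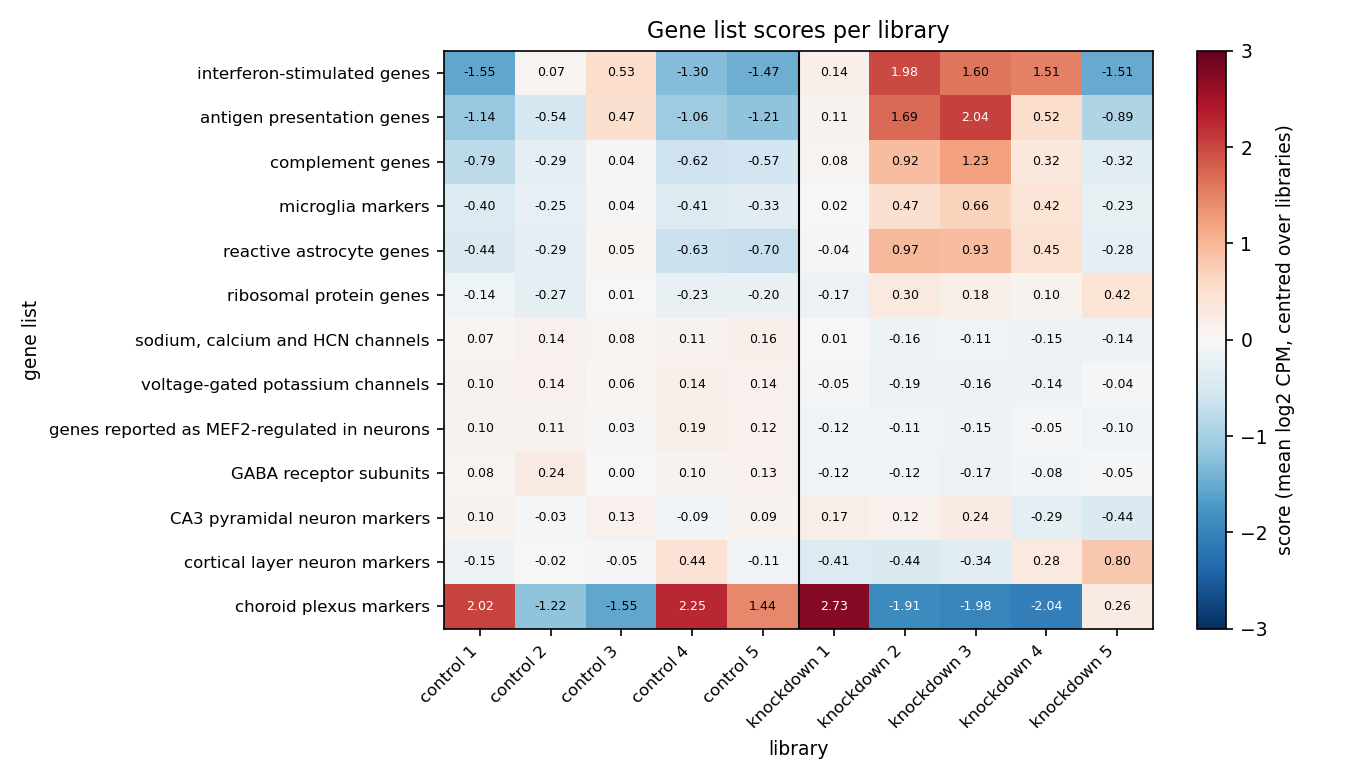
Score of 13 gene lists in each library, as the mean log2 CPM of the list's genes centred over the 10 libraries; the line parts scramble from knockdown libraries and colour runs from blue (low) to red (high). The interferon score runs from -1.55 in scramble library 1 to 1.98 in knockdown library 2, and choroid plexus markers vary widely within both groups.

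Several other groups passed camera upwards. Of 30 ribosomal protein genes, 15 rose, with Rplp0 at 0.46 (SE 0.085) on the log2 scale, and 29 adjusted over the list alone (adjusted p = 0.496 with an estimated correlation). Of 27 nuclear-encoded respiratory chain subunits, Cox5a rose (0.28, SE 0.083), and 0 passed adjusted over the list alone (adjusted p = 0.542 with an estimated correlation). Of 15 p53 target genes, Cdkn1a (1.49, SE 0.262) and Phlda3 (0.64, SE 0.166) rose, and 3 adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Of 16 genes of the unfolded protein and integrated stress response, Xbp1, a transcription factor of that response, rose (0.27, SE 0.082), and 0 passed adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). After the length and GC correction the respiratory chain and unfolded protein lists no longer passed (camera adjusted p = 0.942 for each). The ribosomal list did (camera adjusted p = 2.69e-05, but 0.563 with an estimated correlation). The p53 list did too (camera adjusted p = 0.0203, but 0.485 with an estimated correlation). The ribosomal mean log2 fold change went from 0.341 to 0.133, with 1 gene called, Rplp0 (0.26), and 6 adjusted over the list alone; with RefSeq 3' ends Rplp0 no longer passed (0.24, edgeR adjusted p = 0.0548). Phlda3 (0.395, edgeR adjusted p = 0.251), Xbp1 (0.13, 0.368) and Cox5a (0.18, 0.179) did not pass after the correction.

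Several lists of neuronal ion channels and receptors passed camera downwards without a correction for transcript length, and none of them with an estimated correlation. Of 27 voltage-gated sodium and calcium channel and HCN channel genes, 13 fell, among them Cacna1e (-0.65, SE 0.076) and Scn2a (-0.54, SE 0.081), and Hcn2 rose (0.28). Adjusted over the list alone, 15 fell and 3 rose (adjusted p = 0.317 with an estimated correlation). Of 26 voltage-gated potassium channel genes, 8 fell, including Kcna3 (-1.39, SE 0.238), Kcna2 (-0.55, SE 0.099) and Kcna1 (-0.75, SE 0.169), and Kcnip2 rose (0.26); adjusted over the list alone, 13 fell and 1 rose (adjusted p = 0.317 with an estimated correlation). Hcn2 and Kcnip2 were named after their values were seen. Of 15 AMPA, NMDA and kainate receptor subunits, 6 fell, including Grin2b (731 ± 44.9 to 437 ± 78.9 CPM) and Gria2 (-0.30, SE 0.07), and Grik5 rose (0.26, SE 0.063). Adjusted over the list alone, 7 fell and 1 rose (adjusted p = 0.317 with an estimated correlation). Of 14 GABA receptor subunits, 3 fell over all genes and 3 adjusted over the list alone, including Gabrb2 (110 ± 11.9 to 55.1 ± 17.1 CPM) and Gabrb1 (-0.43, SE 0.072) (adjusted p = 0.317 with an estimated correlation). Of 24 neurexins and synaptic adhesion genes, 5 fell, including the latrophilin Adgrl3 (-0.71, SE 0.105) and the receptor phosphatase Ptprd (-0.52, SE 0.126), and adjusted over the list alone 11 fell and 1 rose (adjusted p = 0.317 with an estimated correlation). The RefSeq gene ends 3563 bp past the GENCODE 3' end of Gabrb2, 3934 bp past that of Kcna1 and 2692 bp past that of Adgrl3. After the length and GC correction, Cacna1e (-0.19, edgeR adjusted p = 0.0857), Scn2a (-0.21, 0.116), Kcna2 (-0.13, 0.606), Grin2b (-0.17, 0.152), Gria2 (0.11, 0.308), Grik5 (0.18, 0.095), Gabrb1 (0.025, 0.864), Ptprd (-0.17, 0.538), Hcn2 (0.10, 0.49) and Kcnip2 (0.16, 0.212) no longer passed. Kcna3 (-1.58, 0.0137), Kcna1 (-0.75, 0.0409), Gabrb2 (-0.96, 0.0326) and Adgrl3 (-0.48, 0.012) did. With RefSeq 3' ends Kcna1 did not pass (-0.52, edgeR adjusted p = 0.0522) and Cacna1e did (-0.23, edgeR adjusted p = 0.0397).

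Of 16 genes reported as MEF2-regulated in neurons, 3 fell over all genes and 3 adjusted over the list alone: the potassium channel gene Kcna1, the postsynaptic scaffold gene Homer1 (-0.31, SE 0.085) and the protocadherin gene Pcdh17 (-0.31, SE 0.086) (adjusted p = 0.317 with an estimated correlation). The score of this list was lower in all 5 knockdown libraries than in all 5 scramble libraries, the library labelled knockdown 5 included (exact two-sided permutation p = 0.0079, 0.0427 after Benjamini-Hochberg adjustment over the 43 lists). The same held, with the same p, for 7 other lists: potassium channels, sodium, calcium and HCN channels, AMPA, NMDA and kainate receptors, GABA receptors, adhesion, perineuronal nets and the MEF2 family. Of 7 genes of the MEF2 family and class IIa histone deacetylases, Hdac9 fell (51 ± 2.48 to 35.3 ± 2.19 CPM), and 2 fell adjusted over the list alone (adjusted p = 0.317 with an estimated correlation). Of 9 genes of the extracellular matrix of perineuronal nets, Tnr (-0.48, SE 0.101) and Has3 (-0.51, SE 0.141) fell, and adjusted over the list alone 4 fell and 1 rose (adjusted p = 0.319 with an estimated correlation). Of 18 cholesterol synthesis genes, 3 fell, among them Lss (-0.34, SE 0.092), and 5 adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). After the length and GC correction, the cholesterol list passed camera among these (adjusted p = 2.69e-05, but 0.485 with an estimated correlation). The sodium, calcium and HCN channel list (adjusted p = 0.104), the potassium channel (0.266), AMPA, NMDA and kainate receptor (0.719), GABA receptor (0.479), adhesion (0.942), MEF2-regulated (0.241), MEF2 family (0.285) and perineuronal (0.266) lists did not. Among the genes, Homer1 (-0.099, edgeR adjusted p = 0.556), Pcdh17 (0.092, 0.431), Tnr (-0.068, 0.623), Has3 (-0.34, 0.21) and Lss (-0.105, 0.534) no longer passed, and Hdac9 did (-0.24, 0.0351).

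Markers of the hippocampal fields did not pass camera: the adjusted p was 0.613 for 8 CA3 markers, 0.322 for 9 CA1 markers, 0.972 for 7 CA2 markers and 0.972 for 8 dentate granule cell markers, with 0 genes called in each, over all genes or adjusted over the list alone. Markers of cortical layers (10 genes, adjusted p = 0.923), the thalamus (8 genes, 0.704), choroid plexus (10 genes, 0.139) and ependyma (9 genes, 0.704) did not pass either, again with 0 genes called either way. In the CA2 and cortical lists the mean and median log2 fold change were above 0 and in the dentate list the mean was, whereas camera's direction was downwards in all 3. Choroid plexus scores ran from -2.04 in knockdown library 4 to 2.73 in knockdown library 1. The CA3 marker score was -0.30 in knockdown library 4 and -0.44 in the library labelled knockdown 5, and between -0.09 and 0.24 in the other libraries.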

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

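All tests of explanations in this part were chosen after the result was seen. In 278 groups of 5 values (library totals, mitochondrial shares, length slopes, list scores and the log2 CPM of each named gene), the gap between the highest or lowest library and its nearest neighbour was set against the group's range. The ratio exceeded 0.71 in 24 groups, where chance gives about 13.9, and groups that share genes are not independent.

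Mef2c was far higher in scramble library 4 than in the other scramble libraries (ratio 0.725), and the library labelled knockdown 5 did not have lower Mef2c. The cortical marker score was also set apart in scramble library 4 (ratio 0.782), and Lamp5, a cortical marker, in the library labelled knockdown 5 (ratio 0.799; 86.1 CPM, against 29 to 36.1 in the other knockdown libraries). A candidate explanation is cortical tissue in the dissected piece. With the cortical score as a covariate the standard error of the Mef2c log2 fold change was 0.0828 instead of 0.30. It was 0.191, 0.293 and 0.33 with the dentate, oligodendrocyte and choroid plexus scores. Without scramble library 4 and the library labelled knockdown 5 it was 0.105. The smaller standard error is therefore not evidence apart from the high Mef2c and high cortical scores of these 2 libraries. Of the 10 cortical genes, all expressed in these libraries, 8 were highest of their group in the library labelled knockdown 5 (Cux2 at 86 CPM). In scramble library 4, 6 were highest of their group (Cux2 at 84.5 CPM). Bcl11b, the most abundant, was lowest of its group in the library labelled knockdown 5 at 117 CPM. That library also had the lowest scores of CA3 (-0.437) and dentate granule cell markers (-0.381) of the 10 libraries. In scramble library 4 they were -0.09 and -0.115. Less hippocampal tissue could lower Bcl11b if hippocampal cells express it, which was not tested. Bcl11b therefore does not decide for or against cortical tissue in the library labelled knockdown 5. A wrong label of that library cannot be told apart from a true one, since 50.2% of the 614 genes called without it, after the length correction, lay on the knockdown side in it. Some values ran as its label says, in genes chosen with this library included. It had Gucy1a2 at 2.42 CPM (scramble libraries 6.79 to 8.38), Dgki at 13.9 (40.5 to 46.0), Adrm1 at 93 (57.4 to 68.2), Eng at 41.9 (26.2 to 27.6) and Cdkn1a at 28.3 (5.50 to 8.31). Its MEF2-regulated score was -0.105, below all scramble libraries (lowest 0.028). These values were not corrected for length, and its length slope (-0.149) was the lowest of the 10 libraries. After the length correction the MEF2-regulated list did not pass camera (adjusted p = 0.241). A weaker knockdown in the library labelled knockdown 5 was not tested.

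Among the other list scores, oligodendrocyte markers were highest in scramble library 3 (ratio 0.774). Ependymal markers were lowest in scramble library 2 (0.717) and highest in knockdown library 1 (0.73). The MEF2 family and histone deacetylase score was highest in scramble library 4 (0.712) and lowest in knockdown library 2 (0.829). The unfolded protein response score was highest in knockdown library 2 (0.782).

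Among single genes, scramble library 3 was highest for C1qa (ratio 0.721), Tmem119 (0.719), S1pr3 (0.837) and Cox5a (0.713). Scramble library 2 was lowest for Nop53 (0.715) and highest for Tenm1 (0.79) and Gabrb1 (0.877). Scramble library 4 was lowest for Cyba (0.74), and scramble library 1 for Penk (0.763). Knockdown library 1 was highest for Ryr2 (0.892), Gabrb2 (0.774) and Tnr (0.75) and lowest for Penk (0.734). Pik3ip1 was lowest in knockdown library 4 (0.774), and Gabrb1 in the library labelled knockdown 5 (0.81).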

How the results depend on the processing

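Unless named as chosen after seeing the data, the alternatives were fixed in advance; the cause of each difference was not tested. The count of called genes, 1766 in the reported analysis, was 3402 with limma-voom, 608 with 1 surrogate variable, 460 at an absolute log2 fold change of at least 0.5 and 3106 at an adjusted p under 0.1. Leaving out 1 library gave 631 (scramble library 2) to 3305 (knockdown library 1) genes, and values between 674 and 1137 without scramble libraries 1, 4 or 5 or knockdown libraries 2, 3 or 4. It stayed within 1.5 times under both other normalizations, both filters, the DESeq2 Wald test (2555) and the dentate and oligodendrocyte covariates. Of 43 lists, 21 passed camera, 0 with an estimated correlation between genes (21 of 21 lost) and 13 with fry. A replicate block gave 1313 genes, a Mef2c log2 fold change of -0.40 and 23 lists; correlations of same-numbered libraries ran from -0.114 to 0.403, not every library correlated best with its own number, and the labels state no pairing.

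Chosen after seeing the data were the following. The length and GC correction left 237 genes and its version with RefSeq 3' ends 260. The covariates gave 2721 genes with the cortical score, 959 with the interferon score (12 lists), 16 with the microglia score (9 lists) and 893 with the choroid plexus score. The microglia score itself differed between the groups (mean -0.27 in scramble and 0.27 in knockdown libraries), so its fit cannot part the group from the score. Leaving out knockdown libraries 2, 3 and 4 gave 0 genes with edgeR, the tool run there (2590 at an unadjusted p under 0.05), and 10 lists; leaving out scramble library 4 and the library labelled knockdown 5 gave 1029 genes, and leaving out scramble libraries 2 and 3 gave 428. Thinning to the lowest total gave 1733. Mef2c passed the threshold without scramble library 4 and the library labelled knockdown 5 (-0.45) and with the cortical score (-0.34), and was 0.18 with the microglia score.

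Directions were reversed as follows, in log2 fold change, first with the length and GC correction and then with RefSeq 3' ends: Mef2a 0.067 and 0.055, Gria2 0.11 and 0.089, Pcdh17 0.092 and 0.073, Slc1a2 0.071 and 0.051, Bcl11b 0.15 and 0.14, Cux2 0.077 and 0.076, the adhesion list 0.0050 and 0.0231. The AMPA, NMDA and kainate receptor list had 0.0017 with the first and -0.016 with the second, where camera's direction was reversed. Gabrb1 (0.025) and Pclo (0.0012) were reversed with the first only. With the second, the camera direction of the unfolded protein list (mean 0.0039) and of the respiratory chain list (0.0085) was reversed. With the microglia score, values were -0.28 for Irf7, -0.86 for Ccl5, 0.61 for Cux2, and as list means -0.61 for infiltrating cells, -0.61 for interferon-stimulated, -0.37 for antigen presentation and -0.29 for chemokine genes; the camera direction of the p53 list (0.025) was reversed. Without knockdown libraries 2, 3 and 4, Ccl5 stood at -0.071 and Cux2 at 0.28. Cux2 stood at 0.12 with a surrogate variable, 0.23 with the interferon score and 0.093 without scramble library 4. The Lamp5 log2 fold change was -0.0719 with limma-voom, -0.11 without scramble library 4 and the library labelled knockdown 5, and -0.23 without the latter alone. When single libraries were left out, Bcl11b ran from -0.21 (without knockdown library 3) to 0.020 (without the library labelled knockdown 5), Cux2 from -0.60 to 0.093 (without scramble library 4) and Lamp5 up to 0.31.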

Other observations

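The splits of the libraries, the test of RefSeq 3' ends and the length slope of glial, vascular and ependymal markers were set before their results were seen; the other tests in this part were chosen after. Among neuronal lists that did not pass camera, the glutamate receptor gene Grm5 fell (log2 fold change -0.44, SE 0.076), with 2 of 7 metabotropic receptors lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0746). Of 13 inhibitory neuron markers, Reln, an extracellular guidance protein (-0.60, SE 0.094), Gad2, a GABA-synthesising enzyme (-0.33, SE 0.066), and Adarb2 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0947); after the length and GC correction none of these 3 passed (-0.24, -0.148 and -0.076, edgeR adjusted p = 0.24, 0.183 and 0.7). Of 20 genes of vesicles and release, 3 fell over all genes and 3 adjusted over the list alone (0.199), among them the active zone genes Pclo (331 ± 26.6 to 227 ± 14.3 CPM, SD, n = 5) and Rims1. Of 21 postsynaptic genes, 5 fell, including Dlgap2 (-0.67, SE 0.102), and the calmodulin-binding gene Nrgn rose (1264 ± 80.7 to 1606 ± 189 CPM, SD, n = 5); adjusted over the list alone 6 fell and 3 rose (0.185). The RefSeq gene ends 5746 bp past the GENCODE 3' end of Dlgap2. Of 29 stress and anxiety-related receptor genes, the glucocorticoid receptor gene Nr3c1 (-0.35, SE 0.084) and the cannabinoid receptor gene Cnr1 (-0.39, SE 0.086) fell, and 2 genes rose, among them Tspo (1.09, SE 0.261), with 2 each way adjusted over the list alone (0.401). Of 20 immediate early genes Fosl2 fell, over all genes and adjusted over the list alone (0.139), and of 17 late activity genes Penk rose and Sorcs3 fell, with 2 each way adjusted over the list alone (0.704). After the length and GC correction, Dlgap2 passed (-0.67, edgeR adjusted p = 0.00359), and Grm5 (-0.146, 0.156), Pclo (0.0012, 0.993), Rims1 (-0.147, 0.212), Nrgn (0.119, 0.302), Nr3c1 (-0.136, 0.238), Cnr1 (-0.209, 0.153), Tspo (0.813, 0.109), Fosl2 (-0.377, 0.109), Penk (0.368, 0.134) and Sorcs3 (-0.186, 0.232) did not.

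Among 12 astrocyte markers, Aldh1l1 (0.29, SE 0.072), Ntsr2 and Atp1b2 rose and the glutamate transporter gene Slc1a2 fell (3263 ± 183 to 2588 ± 256 CPM, SD, n = 5), with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.199). Of 11 endothelial markers, Cldn5 (0.40, SE 0.095) and Ly6c1 (0.58, SE 0.167) rose over all genes and adjusted over the list alone (0.264), and of 10 oligodendrocyte precursor markers Pdgfra fell, with 2 each way adjusted over the list alone (0.881). No gene passed, over all genes or adjusted over the list alone, among 12 oligodendrocyte (0.651), 13 mural and leptomeningeal (0.849), 12 heat shock (0.591) and 13 mitochondrially encoded genes (0.0536); the mean of the mural list was below 0 and its camera direction upwards. Of these called genes none passed after the length and GC correction: Aldh1l1 (0.266, edgeR adjusted p = 0.0848), Ntsr2 (0.197, 0.153), Atp1b2 (0.201, 0.0978), Slc1a2 (0.071, 0.533), Cldn5 (0.158, 0.264), Ly6c1 (0.358, 0.184) and Pdgfra (-0.089, 0.513). After it the inhibitory neuron (0.00799), astrocyte (0.0257) and immediate early gene (0.00241) lists passed camera, with 0 passing with an estimated correlation (adjusted p = 0.485 for each).

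In 100 splits of the libraries into groups of 5, the real one included, 1 gave at least 1766 called genes, the real one. The highest other was 1271, with scramble library 3 exchanged with knockdown library 1. A chance split of exchangeable libraries would thus seldom give as many calls. The labels do not say whether the libraries came from separate animals, and depth also separated the groups. The splits therefore cannot tell the hairpin from anything else that differed between the groups. After the length and GC correction 1 of 100 gave at least 237, again the real one. The highest other gave 224, with scramble library 3 exchanged with the library labelled knockdown 5. For gene lists 5 of 100 gave at least 21, and the highest other was 23, so chance cannot be excluded for the number of lists.

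Long transcripts were lower and short ones higher in the knockdown libraries. Thinning all libraries to the lowest total left 1733 called genes, so their number did not rest on the deeper sequencing itself. Thinning keeps each gene's share of the counts, so it cannot say whether the trend came with the depth difference. In 15 neuronal genes under 3 kb the median log2 fold change was 0.11 (95% bootstrap interval 0.01 to 0.18). Medians of all tested genes were 0.26 under 1 kb, 0.19 at 1 to 2 kb and 0.06 at 2 to 4 kb. Without genes matched for length, the neuronal median cannot decide on a smaller share of neuronal RNA. Coverage that depends on length and GC content, as RNA breakage before polyA selection could give, predicts the trend in every cell type. Among 81 markers of glial, vascular and ependymal cells in 7 lists, each list with its own level, the log2 fold change per doubling of length was -0.213 (95% bootstrap interval -0.272 to -0.152), against -0.171 in all tested genes, so the trend is not confined to neuronal genes. A biological effect on long transcripts of all these cells stays open, untested. Of the 1766 called genes 171 stayed called after the correction, which removes the trend whatever its cause. Of genes called lower after it, 55 of 130 had a RefSeq 3' end at least 1 kb past the annotated end, against 752 of 13998 others (odds ratio 12.9, 95% interval 8.88 to 18.7), so understated length may account for part of these. With lengths up to the RefSeq ends, 27 of the 53 whose end lay 1 to 20 kb past were still called lower. Gucy1a2 (-1.43, SE 0.165, edgeR adjusted p = 0.00288) and Dgki (-0.93, SE 0.091, edgeR adjusted p = 0.00107) were among them. They fell further than the fitted trend gives for their length. The correction does not change which reads were counted, and the annotation used for counting is not given. Coverage therefore stays open as a cause of their fall. All 92 tested genes with a RefSeq end 8 to 20 kb past had a median log2 fold change of 0.31 after this second correction, so these ends may overstate length for many. Genes with near 3' ends that stayed called under both corrections were 104, or 5.89% of all called; this narrowly exceeds the 5% set after an earlier version of the test was seen, and a biological effect of the hairpin stays an untested hypothesis for them.

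Immune gene lists passed camera upwards, none with an estimated correlation, and the library labelled knockdown 5 scored within the range of the scramble libraries in the lists named below. The length trend does not account for this, since the interferon-stimulated genes kept a mean log2 fold change of 1.59 after the correction, against 1.66 before. The call of Rtp4 ended with little change in its log2 fold change (2.05, SE 0.521, before; 1.95, SE 0.515, after; edgeR adjusted p = 0.0935); its unadjusted p was 0.003 before and 0.00385 after. Whether the Mef2c hairpin raised them cannot be told apart from variation between injections, as the exact two-sided permutation p of the interferon score was 0.111 and the library labelled knockdown 5 scored as low as scramble libraries 1, 4 and 5. The exact p was 0.0238 for the microglia and complement scores, 0.0317 for reactive astrocyte and 0.0397 for activated microglia genes, and from 0.0788 to 0.0948 after Benjamini-Hochberg adjustment; it was 0.0714 for antigen presentation, 0.0635 for infiltrating cell and 0.0556 for chemokine scores. Reactions to the virus or the surgery that differ between animals stay open, since no label records them.

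Of the genes called without a given library after the length correction, 22.2% of 887 lay on the knockdown side in knockdown library 1, which had the lowest Mef2c of all 10. The shares were 100%, 96.8% and 89.3% for knockdown libraries 2, 3 and 4, and from 0% to 17.1% for the scramble libraries.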
